A study of Mus musculus with 15 samples.

How the data were processed

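RNA from progenitor cells of mouse bone marrow was sequenced in 15 libraries. Per the labels, cells were sorted as common myeloid progenitors (CMP; lineage-negative, Sca1-negative, CD117-positive, CD34-positive, low for CD16/32) or as granulocyte-monocyte progenitors (GMP; the same gate, high for CD16/32). Each sort was made from Trappc1 knockout (KO) and wild-type (WT) mice. The groups were WT CMP (n = 4), KO CMP (n = 4), WT GMP (n = 4) and KO GMP (n = 3). Group and library number were taken from the sample titles and characteristics. KO GMP libraries were numbered 1, 3 and 4; a KO GMP library numbered 2 was not used here. The labels do not say whether libraries came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

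Per the labels' protocols, libraries were made with the SMARTER mRNA-Seq kit. Per the submitters' processing notes, reads were aligned with HISAT to mm10, with versions not given. The counting tool, its annotation and its filters are not given in the sources used here. The deposited value is an expected count (an estimated count) per gene symbol, not scaled between libraries. Of 40915 values between 1 and 40 in the files, 38% were multiples of 4, against 25% for an even spread, so 1 sequenced fragment was taken to be worth about 4 units. Library totals ran from 61.3 to 120.3 M units, which is about 15.3 to 30.1 M fragments after division by 4. Of 23337 gene symbols, 25 had been turned into dates, and these kept the names in the files. All pairs of libraries were checked for duplicated columns, and none was found. Gene positions come from GENCODE M21 on GRCm38.

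Counts scaled by library size (CPM) and tests used R 4.3.3 with edgeR 4.0.16. Values were rounded, genes were kept by filterByExpr on the groups (15181 genes), and libraries were scaled by TMM. All libraries entered a single quasi-likelihood fit with 1 coefficient per group, which leaves 11 residual degrees of freedom. The contrasts were KO against WT in CMP, KO against WT in GMP, the difference between these effects (CMP minus GMP), and GMP against CMP within each genotype. P-values are two-sided and adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Adjusted p-values are from edgeR unless another tool is named. Standard errors (SE) of log2 fold changes come from the same fit. Single values of Trappc1 were compared with an exact permutation test of mean log2 CPM, over all splits of the libraries of a cell type, without pairing by number. Correlations between log2 fold changes are across genes, and genes are not independent replicates.

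For 37 gene lists, camera (limma 3.58.1) used a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 36 lists with at least 5 tested genes. Camera with an estimated correlation and fry were run beside it. The lists cover the TRAPP complex, ER to Golgi transport, ER chaperones, ATF4 targets, p53 targets, cell cycle, replication, CDK inhibitors, apoptosis, calcium handling, immediate early genes, heat shock, stem cells, primary granules, late neutrophils, monocytes, dendritic cells, erythroid cells, megakaryocytes, mast cells with basophils and eosinophils, B cells, T and NK cells, stroma, interferon response, cholesterol synthesis, ribosome biogenesis, glycolysis, autophagy, oxidative stress, cytokine receptors, myeloid transcription factors, sorting markers, sex-linked genes, mitochondrial transcripts, ribosomal proteins, oxidative phosphorylation and histones. List symbols missing from the files were matched through RefSeq synonyms, for example Chil3 to Chi3l3, Mzb1 to 2010001M09Rik and Jchain to Igj. Of the mitochondrial transcripts, 0 were among the tested genes.

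The named genes are Trappc1, the 10 genes higher and the 10 lower with the largest log2 change among those past the threshold with at least 5 CPM and no overlap between groups, up to 4 members of each described list by smallest p, 5 and 5 genes plus the sorting markers for GMP against CMP, and the 5 smallest p-values per direction for the difference between cell types. Unnamed clones and pseudogenes were left out, and single genes that the rule names but the text omits are not reported here. Groups, contrasts, lists, the rule for named genes and most alternatives were chosen before the data were examined.

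The libraries were also taken as 2 number sets, 1 and 2 against 3 and 4. This split was chosen after the data were seen, because the WT libraries alone part that way. A fit with 1 coefficient for each of the 8 combinations of group and number set (7 residual degrees of freedom) gave the KO effect in each set, and the difference between sets was tested in that fit. In GMP, numbers 1 and 2 hold a single KO library, which is assumed to vary like the others. Number set and sequencing batch are not linked by the labels. The same naming rule and lists were applied to these contrasts.

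Deviations of libraries from their group mean correlated across genes for the same number at 0.127 to 0.419 in all 14 pairs of libraries, above the limit of 0.1, and 12 of 14 were highest for the library's own number. The numbers were therefore taken to pair libraries, and a block by number was run as an alternative.

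Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no low-count filter, a stricter filter (at least 10 units in every library of at least 1 group), only the 2 groups compared, a block by library number, a block by genotype and number, a threshold of 1%, glmTreat at 1.5-fold, and leaving out each library in turn. Number set as a covariate, values divided by 4, and fits on a number set alone were chosen after the data were seen. Where a side of a comparison held no fragment, a bound was computed from a floor of 3 fragments over all libraries of that side. With 1 to 3 fragments or a part of one, a ratio is given with a 95% exact binomial interval. Such intervals and floors cover counting error only, since reads copied during amplification cannot be told apart here.

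The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. At 2-fold it recovered 89% in CMP, 80% in GMP and 87% for GMP against CMP in WT, with 7, 9 and 6 false calls. Within numbers 3 and 4 it recovered 98% in CMP and 98% in GMP, and within numbers 1 and 2 it recovered 86% in GMP. At 4-fold it recovered 100% in each of these comparisons. Each simulated gene had a single mean over the libraries of a cell type or genotype, with no number-set structure. Changed genes had at least 5 CPM. These shares can therefore overstate recovery in the real libraries. Camera called a raised list and 0 of 20 unchanged lists. Simulated genes were drawn independently, so this does not show how camera behaves on lists whose genes vary together.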

Results

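The data are gene-level estimated counts from 15 libraries of sorted mouse bone marrow progenitors, CMP and GMP, from Trappc1 KO and WT mice. Trappc1 encodes a core subunit of the TRAPP complexes, which tether vesicles between the endoplasmic reticulum (ER) and the Golgi. Mean library totals were 88.26 M units in WT CMP (n = 4), 88.64 in KO CMP (n = 4), 82.52 in WT GMP (n = 4) and 84.88 in KO GMP (n = 3). Values after ± are standard errors for log2 fold changes and standard deviations for CPM.

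Trappc1 (ENSMUSG00000049299.14, chromosome 11, 69323980 to 69325793, plus strand, GRCm38) was lower in every KO library than in every WT library of the same cell type. In CMP it measured 8.63 ± 4.65 CPM in KO (n = 4) and 22.1 ± 4.13 CPM in WT (n = 4). The exact permutation test gave a two-sided p of 0.0286, the smallest that the 70 splits allow. The splits here and in GMP exchange genotype freely and leave out the library numbers, which were taken to pair libraries. Swaps kept within numbers would be fewer and allow no p this small. In GMP it measured 18.5 ± 10.7 CPM in KO (n = 3) and 35.7 ± 4.54 CPM in WT (n = 4), with an exact two-sided p of 0.0571, the smallest that 35 splits allow, so this test cannot reach 0.05. The WT CMP libraries 1 to 4 held 18.4, 26.2, 18.8 and 25.2 CPM, and the KO CMP libraries held 5.56, 3.83, 11.7 and 13.4 CPM. The WT GMP libraries held 41.3, 37, 30.9 and 33.3 CPM, and KO GMP libraries 1, 3 and 4 held 6.09, 24.1 and 25.2 CPM. The log2 change over all libraries was -1.36 ± 0.41 in CMP (adjusted p = 0.243) and -0.95 ± 0.45 in GMP (adjusted p = 0.77). With DESeq2 Trappc1 passed in CMP (-1.36, adjusted p = 0.0267) and in CMP numbers 3 and 4 (-0.81, adjusted p = 0.017). In CMP it was -2.25 ± 0.21 in numbers 1 and 2 (adjusted p = 1.03e-05) and -0.80 ± 0.19 in numbers 3 and 4 (adjusted p = 0.263). In GMP it was -2.69 ± 0.27 in numbers 1 and 2 (adjusted p = 3.61e-05) and -0.38 ± 0.19 in numbers 3 and 4 (adjusted p = 1). The KO effect on Trappc1 differed between the number sets by -1.45 ± 0.28 in CMP (adjusted p = 0.00689) and by -2.30 ± 0.32 in GMP (adjusted p = 0.000774). Without KO GMP library 1 the change over all GMP libraries was -0.53. Which part of Trappc1 is deleted is not given in the sources used here. Gene-level values can hold reads from remaining exons, so these levels do not measure how much function was lost.

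**Figure D1:**
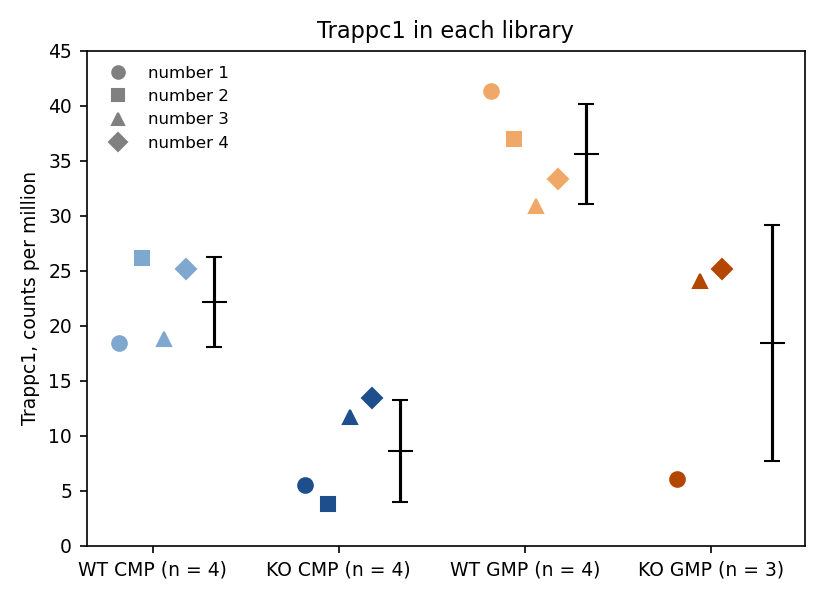
Trappc1 in CPM (vertical axis) in each library, by group (horizontal axis), with marker shape for the library number and the group mean and standard deviation at the right of each group. KO CMP libraries lie between 3.83 and 13.4 and WT CMP libraries between 18.4 and 26.2.

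The number sets part the libraries beyond Trappc1. Among WT libraries alone, the first principal component held 61.5% of the variance in CMP and 50.3% in GMP, and it put numbers 1 and 2 on the other side of numbers 3 and 4 in each cell type. Over all libraries, PC1 (49.7% of the variance) parted CMP from GMP, except that KO GMP library 1 lay at -17.2, away from the other GMP libraries at 80.3 to 86.5. KO CMP libraries 1 and 2 lay at -95.4 and -103.9, and the other CMP libraries between -57.4 and -37.5. KO libraries 1 and 2 of CMP and library 1 of GMP also held Xist, the X-inactivation RNA, at 109, 204 and 123 CPM, against at most 2.17 CPM in the other libraries. KO effects are therefore given over all libraries and within each number set. Differences between the sets are numbers 1 and 2 minus numbers 3 and 4.

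**Figure D2:**
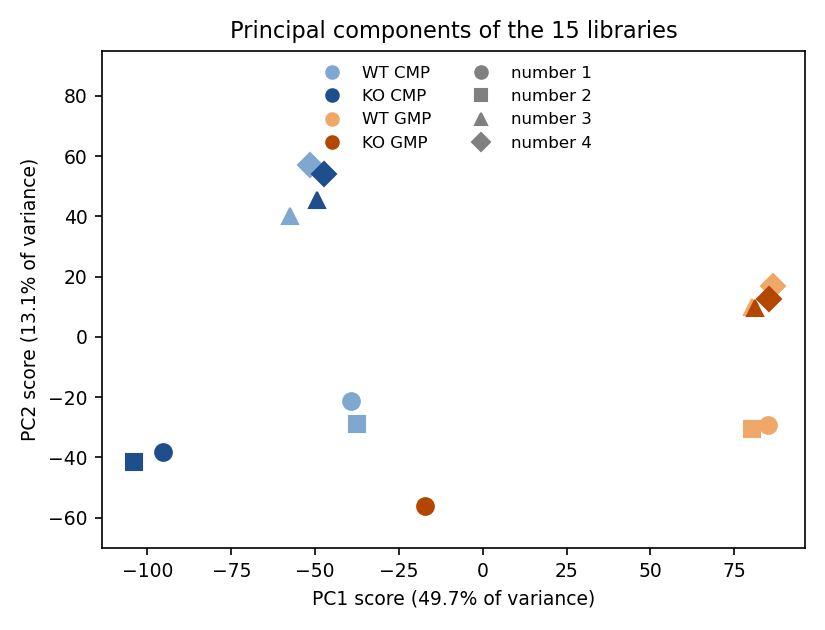
Scores of the 15 libraries on PC1 (horizontal axis, 49.7% of the variance) and PC2 (vertical axis, 13.1% of the variance), with colour for the group and shape for the library number. KO GMP library 1 lies at -17.2 on PC1, between the CMP and the GMP libraries.

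What loss of Trappc1 changes in CMP is the main question of the series. Over all libraries edgeR called 0 genes in KO CMP, so the values here come from number sets chosen after the data were seen. KO CMP libraries 1 and 2 also stood apart by Xist (109 and 204 CPM) and on PC1 (-95.4 and -103.9). An effect of genotype in them cannot be separated from what else sets these libraries apart. In KO CMP libraries 1 and 2 (n = 2), genes of the granule list fell against WT libraries 1 and 2 (n = 2). Neutrophil elastase (Elane) changed by -3.71 ± 0.15 log2 units, myeloperoxidase (Mpo) by -2.08 ± 0.08, proteinase Prtn3 by -2.18 ± 0.08 and the glutathione transferase Gstm1 by -1.99 ± 0.07. In numbers 3 and 4 (n = 2 in each genotype) Elane measured -0.07 ± 0.14 (adjusted p = 0.878) and Mpo -0.01 ± 0.08 (adjusted p = 0.988), and neither passed. The difference between the number sets passed for Elane (-3.64 ± 0.20, adjusted p = 7.48e-07) and for Mpo (-2.07 ± 0.11, adjusted p = 4.87e-07). Stem cell and multipotent progenitor genes rose in the same KO libraries, among them Angpt1 (0.97 ± 0.08), Meis1 (0.99 ± 0.09) and Hlf (0.84 ± 0.10).

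Over all libraries edgeR called 0 genes higher and 0 lower in KO CMP, while 1761 genes had an unadjusted p under 0.05 (711 higher, 1050 lower) where chance gives 759, and DESeq2 called 133 higher and 227 lower. The 1761 became 1119 without WT CMP library 1, 2697 with a block by library number and 2731 with the number set as a covariate. The smallest adjusted p was 0.192. Camera called 18 of 36 lists over all libraries in CMP (9 up, 9 down), 0 with an estimated correlation (smallest adjusted p = 0.209 with an estimated correlation) and 1 by fry. Without WT CMP library 4, edgeR called 2 higher and 48 lower, and without KO CMP library 1 it called only Tor1aip1, lower. In numbers 1 and 2 edgeR called 1249 genes higher and 1552 lower, a share higher of 44.6% that became 50.9% with RLE factors. In numbers 3 and 4 it called 1 higher (Chi3l3) and 0 lower, with 1729 genes at an unadjusted p under 0.05, and DESeq2 called 73 higher and 65 lower. Chi3l3 (1.09, range 0.97 to 1.22) was not called without any of WT CMP libraries 3 and 4 and KO CMP libraries 3 and 4. Without KO CMP library 3 edgeR called 0 higher and 4 lower. The KO effect differed between the number sets for 1160 genes (463 higher, 697 lower in numbers 1 and 2). The 463 fell to 261, 287, 278 and 208 without WT CMP library 2, WT CMP library 3, KO CMP library 3 and KO CMP library 4. Without a WT CMP library of numbers 1 and 2 the count of genes higher fell to 814 (library 1 left out) or 722 (library 2 left out).

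**Figure D3:**
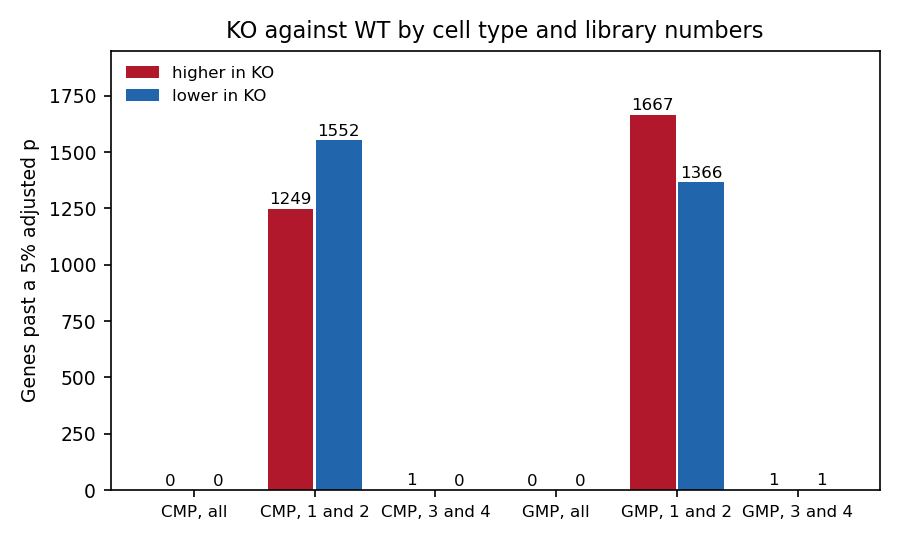
Genes past an adjusted p of 5% (vertical axis) for KO against WT in each cell type, over all libraries and within library numbers 1 and 2 or 3 and 4 (horizontal axis), with bars for genes higher and lower in KO. Counts are 1249 and 1552 in CMP numbers 1 and 2 and 1 and 0 in CMP numbers 3 and 4.

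The granule list, primary granule proteins and regulators of the GMP stage, fell as a whole in KO CMP numbers 1 and 2. All 17 tested members were lower, 17 also when adjusted over the list alone (camera adjusted p = 9.42e-80, and adjusted p = 0.00053 with an estimated correlation). Over all libraries 0 of 17 passed, and adjusted over the list alone 0 rose and 14 fell, with camera at 1.79e-16 and an adjusted p = 0.209 with an estimated correlation. Of 19 late neutrophil genes tested in numbers 1 and 2, 13 fell and 1 rose, or 15 and 1 adjusted over the list alone (camera adjusted p = 4.49e-46, and adjusted p = 0.000193 with an estimated correlation). The calprotectin subunits S100a8 (-6.57 ± 0.37) and S100a9 (-5.22 ± 0.24), the granule protein Ngp (-6.38 ± 0.29) and the chitinase-like Chi3l3 (-5.24 ± 0.17) were among the genes with the largest change. Chi3l3 in numbers 3 and 4 rose by 1.09 ± 0.13 (adjusted p = 0.0258), from 2.38 and 2.01 CPM in WT to 4.95 and 4.42 CPM in KO. Ficolin Fcnb (-5.96 ± 0.51), the lectin Clec4a2 (-5.49 ± 0.42), the scavenger receptor Olr1 (-5.64 ± 0.28) and the RNA-binding Lin28a (-5.95 ± 0.46) also fell in numbers 1 and 2. Fcnb held 0 CPM in KO CMP library 1, and its change ran from -13.98 to -5.01 with 1 library left out. The acyltransferase Mogat2 was 377-fold lower (counting interval 67.4 to 15000) and the lectin Clec4b2 was 207-fold lower (36.7 to 8190), each with 1 fragment left in KO. WT CMP libraries 1 and 2 themselves held more of these transcripts than WT libraries 3 and 4, by 1.74 ± 0.14 for Elane and 4.27 ± 0.32 for S100a8.

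Myeloid regulators moved in the same KO libraries. Of 19 transcription factors, 9 fell and 3 rose, or 10 and 3 adjusted over the list alone (camera adjusted p = 1.06e-05, and adjusted p = 0.0135 with an estimated correlation). Gfi1 (-1.87 ± 0.08), Cebpe (-3.05 ± 0.22), Cebpd (-1.81 ± 0.11) and Irf8 (-1.86 ± 0.17), regulators of granulocyte and monocyte fate, fell, and Gata2 rose (1.02 ± 0.11). Of 22 monocyte and macrophage genes, 14 fell and 2 rose, or 16 and 4 adjusted over the list alone (camera adjusted p = 8.72e-14, but adjusted p = 0.108 with an estimated correlation). The M-CSF receptor Csf1r changed by -2.07 ± 0.14 and the integrin Itgam by -1.61 ± 0.11. Of 15 cytokine receptors, 6 fell and 3 rose, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0379, but adjusted p = 0.108 with an estimated correlation). Of 21 mast cell, basophil and eosinophil genes, 10 fell and 2 rose, the same counts adjusted over the list alone (camera adjusted p = 0.00141, but adjusted p = 0.108 with an estimated correlation). The basophil protease Prss34 changed by -4.30 ± 0.47. Of the sorting markers, the CD16 gene Fcgr3 (-2.76 ± 0.15) and the CD32 gene Fcgr2b (-0.89 ± 0.07) fell, and Ly6a (1.14 ± 0.20) and Cd34 (0.41 ± 0.07) rose.

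Of 19 stem cell and multipotent progenitor genes in KO CMP numbers 1 and 2, 12 rose and 0 fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 3.41e-09, and adjusted p = 0.0053 with an estimated correlation). Esam, a junction protein of stem cells, changed by 1.48 ± 0.20. Of 18 megakaryocyte genes 9 rose and 0 fell, or 10 and 0 adjusted over the list alone (camera adjusted p = 1.29e-06, but adjusted p = 0.108 with an estimated correlation), with Selp at 1.30 ± 0.11, the thrombin receptor F2r at 1.27 ± 0.13 and Vwf at 0.81 ± 0.12. Of 23 erythroid genes 8 rose and 2 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.0386, but adjusted p = 0.435 with an estimated correlation). Of 28 genes of the G2 and M phases 12 rose and 0 fell, or 17 and 0 adjusted over the list alone (camera adjusted p = 0.000255, but adjusted p = 0.108 with an estimated correlation), with the cyclin Ccnb1 at 0.51 ± 0.08.

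Of 28 ER chaperone and unfolded protein response genes in KO CMP numbers 1 and 2, 21 fell and 0 rose, or 27 and 0 adjusted over the list alone (camera adjusted p = 4.33e-12, but adjusted p = 0.1 with an estimated correlation). In numbers 3 and 4 the list median was 0.11, 19 of 28 members were positive and 0 passed (camera adjusted p = 0.0697). The effect differed between the sets for 17 genes, all lower in numbers 1 and 2 (camera adjusted p = 1.23e-14, but adjusted p = 0.0768 with an estimated correlation). Hspa5 measured 0.28 ± 0.08 in numbers 3 and 4 (adjusted p = 0.304), and its effect differed between the sets by -1.06 ± 0.12 (adjusted p = 0.000134). In WT CMP 17 of 28 were higher in numbers 1 and 2 than in 3 and 4, with Hspa5 at 0.63 ± 0.08. In KO against WT numbers 1 and 2 the chaperone Hspa5 changed by -0.78 ± 0.08, the disulfide isomerase P4hb by -0.72 ± 0.07 and the stress regulator Xbp1 by -0.77 ± 0.08. Of 41 ER to Golgi transport genes, 14 fell and 1 rose, or 16 and 1 adjusted over the list alone (camera adjusted p = 0.0136, but adjusted p = 0.108 with an estimated correlation), among them the Golgi stacking protein Gorasp1 (-0.61 ± 0.07). Of 14 TRAPP subunits 3 fell and 0 rose, 3 also adjusted over the list alone, namely Trappc1, Trappc10 (-0.52 ± 0.10) and Trappc2 (-0.72 ± 0.20), and the list was not called (camera adjusted p = 0.0551). Trappc2 was not called without WT CMP library 2 or without KO CMP library 2 (-0.44), and ran to -1.06 without KO CMP library 1. Of 24 cholesterol synthesis genes 14 fell and 0 rose, or 16 and 0 adjusted over the list alone (camera adjusted p = 1.37e-06, and adjusted p = 0.00668 with an estimated correlation), with the farnesyl diphosphate synthase Fdps at -1.15 ± 0.11. Of 29 autophagy and lysosome genes 12 fell and 2 rose, or 16 and 2 adjusted over the list alone (camera adjusted p = 0.000173, but adjusted p = 0.108 with an estimated correlation).

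Genes of the p53 and interferon responses rose in these libraries. Of 25 p53 targets, 10 rose and 1 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 7.96e-07, and adjusted p = 0.00949 with an estimated correlation), with the CDK inhibitor Cdkn1a at 1.36 ± 0.11, Zmat3 at 2.20 ± 0.17 and Phlda3 at 2.69 ± 0.28. Of 24 interferon response genes, 17 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 6.31e-09, and adjusted p = 0.00668 with an estimated correlation), with the antiviral Rsad2 at 1.30 ± 0.11 and Irf7 at 1.11 ± 0.12. The WT reference itself was low for this list, with 21 of 24 members lower in WT CMP libraries 1 and 2 than in 3 and 4 and Rsad2 at -1.77 ± 0.11. The interferon list was also called upward in numbers 3 and 4 (camera adjusted p = 2.03e-09, and adjusted p = 0.0226 with an estimated correlation), with 0 members past the all-gene threshold and 5 higher adjusted over the list alone. Ribosome biogenesis was called upward in numbers 3 and 4 as well (camera adjusted p = 2.73e-15, and adjusted p = 0.045 with an estimated correlation), with 0 of 22 members passing over all genes and 16 higher adjusted over the list alone. In all, camera called 15 lists in CMP numbers 3 and 4 (11 up, 4 down), 2 with an estimated correlation. The other 9 upward were ATF4 targets, DNA replication, immediate early genes, heat shock, late neutrophil genes (median -0.02), erythroid genes, glycolysis, ribosomal proteins and oxidative phosphorylation. Monocyte, dendritic cell, T and NK and cytokine receptor genes were called downward. Of 22 ATF4 and CHOP targets 5 rose and 0 fell in numbers 1 and 2, 5 also adjusted over the list alone (camera adjusted p = 0.0474, but adjusted p = 0.168 with an estimated correlation). The genes with the largest rise in numbers 1 and 2 were Xist (6.71 ± 0.43), the ETS factor Etv4 (4.44 ± 0.75) and genes typical of stromal cells. These were the collagens Col1a1 (4.07 ± 0.96), Col6a2 (4.06 ± 0.64), Col6a3 (3.91 ± 0.75) and Col3a1 (3.80 ± 0.75), with Sparc (3.83 ± 0.45), Chrdl1 (3.81 ± 1.06), Cxcl14 (3.72 ± 0.65) and adiponectin (Adipoq, 3.68 ± 1.16). Col1a1, Chrdl1 and Adipoq were not called without WT CMP library 1, WT CMP library 2 or KO CMP library 2, nor Adipoq without KO CMP library 1, nor Col3a1 without WT CMP library 1. Of 13 stromal and endothelial list genes 7 rose and 1 fell (Vcam1, -2.28 ± 0.40, or -3.58 without KO CMP library 2), the same counts adjusted over the list alone (camera adjusted p = 0.000458, but adjusted p = 0.108 with an estimated correlation). Of the remaining lists in numbers 1 and 2, ribosomal proteins (0 of 85 higher, 2 lower, 0 and 0 adjusted over the list alone) were called downward (camera adjusted p = 0.0251, but adjusted p = 0.832 with an estimated correlation). The 5 sorting markers were called downward though their median was 0.18 and their mean -0.39 (camera adjusted p = 0.043, but adjusted p = 0.24 with an estimated correlation). Camera did not call DNA replication (3 higher, 1 lower of 28; 0.171), CDK inhibitors (2 and 1 of 9; 0.153), apoptosis (3 and 5 of 25; 0.661), calcium handling (1 and 5 of 33; 0.51) or immediate early genes (3 and 2 of 23; 0.708). It did not call heat shock (1 and 2 of 12, 0.457), dendritic cells (1 and 1 of 17, 0.38), B lineage (0 and 0 of 15, 0.962), T and NK lineage (1 and 0 of 17, 0.292) or ribosome biogenesis (3 and 0 of 22, 0.0675). Nor did it call glycolysis (3 and 5 of 16, 0.661), oxidative stress (5 and 2 of 17, 0.667), oxidative phosphorylation (2 and 1 of 87, 0.962), histones (0 and 3 of 65, 0.194) or sex-linked genes (1 and 1 of 6, 0.82). Sparc stood at 12.5 and 18.1 CPM in KO CMP libraries 1 and 2 and at most 1.49 CPM in the other CMP libraries.

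**Figure D4:**
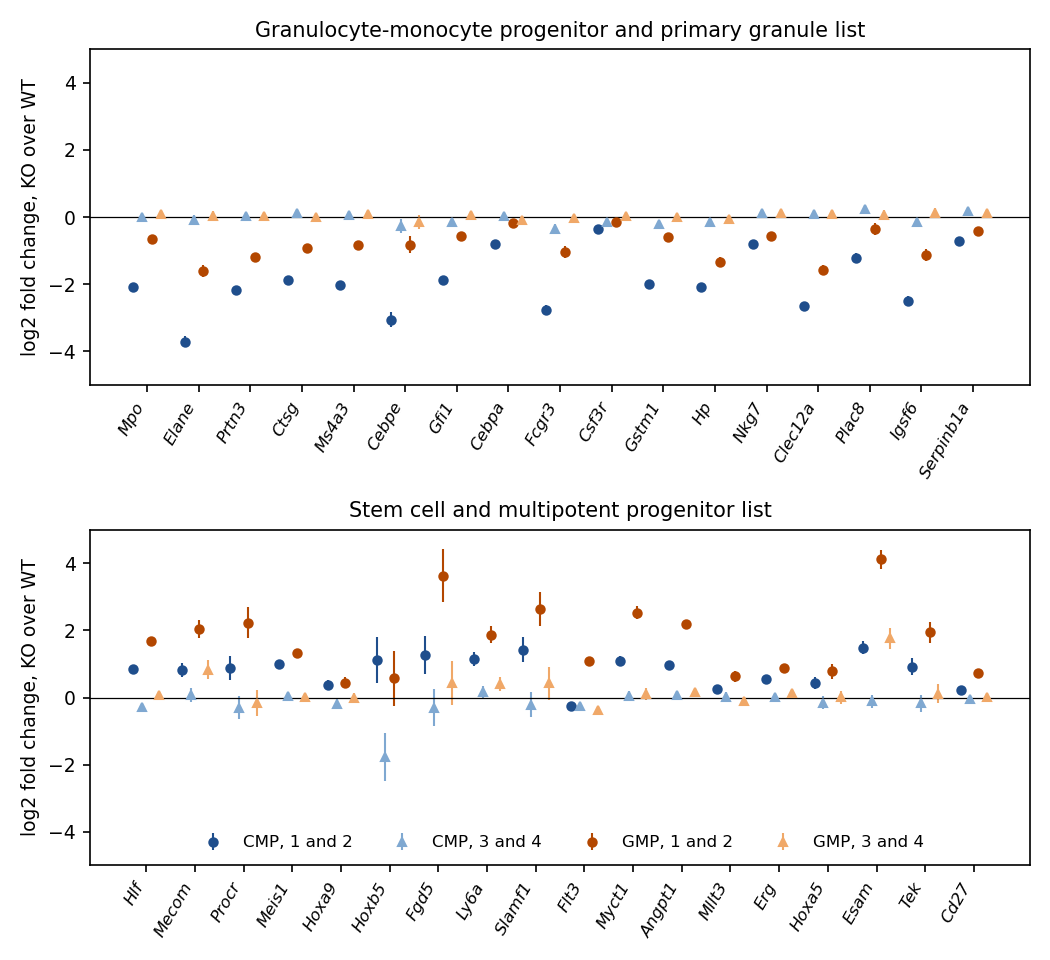
Log2 fold changes of KO over WT with standard errors (vertical axis) for genes of 2 lists (horizontal axes), by cell type (colour) and library numbers (circles for 1 and 2, triangles for 3 and 4), without points where a side held no fragment. Elane lies at -3.71 in CMP numbers 1 and 2 and at -0.07 in CMP numbers 3 and 4.

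In GMP the same question was asked of 3 KO and 4 WT libraries. KO GMP library 1 (n = 1) differed widely from WT GMP libraries 1 and 2 (n = 2), while in numbers 3 and 4 edgeR called 1 gene higher and 1 lower. In library 1, stem and megakaryocyte genes rose, with the junction protein Esam at 4.12 ± 0.29 and Vwf at 3.04 ± 0.14. Late neutrophil genes fell, with Chi3l3 at -5.57 ± 0.20, Ngp at -5.28 ± 0.35 and S100a9 at -4.38 ± 0.30. In numbers 3 and 4 (n = 2 in each genotype) the calcium-binding S100a6 fell by 1.08 ± 0.14 on the log2 scale (adjusted p = 0.0414), below its change of -0.16 ± 0.17 in numbers 1 and 2 (difference between the sets 0.92 ± 0.22, adjusted p = 0.0182).

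Over all libraries edgeR called 0 genes higher and 0 lower in KO GMP, with 985 genes at an unadjusted p under 0.05 (681 higher, 304 lower; 759 by chance) and a smallest adjusted p of 0.161 (Tpm4). The 985 became 537 without KO GMP library 1, 1208 with a block by library number and 1582 with the number set as a covariate. DESeq2 called 48 higher and 12 lower. With the number set as a covariate edgeR called Col6a2, Slc6a15, Trib1 and Evc2 higher and Tpm4 lower. In numbers 1 and 2 edgeR called 1667 genes higher and 1366 lower, and without WT GMP library 1 the lower count was 757. In numbers 3 and 4 it called 1 higher (the unnamed gene model Gm8801, which held no counts in these WT libraries) and 1 lower (S100a6), with 789 genes at an unadjusted p under 0.05, and DESeq2 called 13 and 30. S100a6 (-1.12 to -1.04) was not called without any of WT GMP libraries 3 and 4 and KO GMP libraries 3 and 4. Without KO GMP library 3 edgeR called 5 others lower. Without WT GMP library 3 or 4, 3 or 2 genes were called higher. The KO effect differed between number sets for 1614 genes (952 higher, 662 lower in numbers 1 and 2). The 662 fell to 372, 330, 427, 349 and 324 without WT GMP library 1, 3 or 4 or KO GMP library 3 or 4. The genes called in numbers 1 and 2 overlapped between the cell types, with 789 higher in both and 794 lower in both, while 5 and 14 moved in opposite directions. Independent calls would give 137 and 140. Libraries of the same number vary together (correlation of deviations 0.419 for KO CMP 1 with KO GMP 1), so more would be shared with no KO effect. The calls, list tests, overlaps and set differences that use GMP numbers 1 and 2 rest on KO GMP library 1, whose spread is assumed, and cannot separate an effect of genotype from what sets that library apart.

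Of 19 stem cell genes in KO GMP library 1, 17 rose and 0 fell, or 18 and 0 adjusted over the list alone (camera adjusted p = 1.51e-27, and adjusted p = 0.000377 with an estimated correlation), with Angpt1 at 2.18 ± 0.10. Of 18 megakaryocyte genes 14 rose and 0 fell, or 15 and 1 adjusted over the list alone (camera adjusted p = 7.25e-22, and adjusted p = 0.0116 with an estimated correlation), with F2r at 4.00 ± 0.18. Of 17 dendritic cell and antigen presentation genes 10 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 3.79e-07, but adjusted p = 0.171 with an estimated correlation). The class II gene H2-Eb1 changed by 3.48 ± 0.36 and its regulator Ciita by 4.15 ± 0.47. Of 23 erythroid genes 11 rose and 1 fell, or 11 and 2 adjusted over the list alone (camera adjusted p = 6.41e-06, but adjusted p = 0.113 with an estimated correlation). Of 21 mast cell, basophil and eosinophil genes 8 rose and 3 fell, or 8 and 5 adjusted over the list alone (camera adjusted p = 0.0479, but adjusted p = 0.294 with an estimated correlation). The mast cell protease Cma1 changed by 5.04 ± 0.70, and the tryptase Tpsb2, whose reads can be shared with its paralog, was 1010-fold higher (counting interval 44.8 to 10100). The same list was called downward in numbers 3 and 4 (camera adjusted p = 1.09e-13, and adjusted p = 0.0107 with an estimated correlation), with 0 of 21 passing over all genes and 9 lower adjusted over the list alone. Camera did not call B lineage (1 higher, 0 lower of 15; 0.534) or T and NK lineage (4 and 0 of 17; 0.0812) in library 1. In numbers 3 and 4 the basophil protease Mcpt8 measured -0.79 ± 0.12 (adjusted p = 0.0653).

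Of 17 granule genes in KO GMP library 1, 14 fell and 0 rose, 14 also adjusted over the list alone (camera adjusted p = 2.73e-13, and adjusted p = 0.0296 with an estimated correlation), with Prtn3 at -1.19 ± 0.10 and Elane at -1.60 ± 0.18. Of 19 late neutrophil genes 13 fell and 3 rose, or 15 and 3 adjusted over the list alone (camera adjusted p = 4.08e-18, and adjusted p = 0.00179 with an estimated correlation), with S100a8 at -4.72 ± 0.45 and Fcnb at -4.48 ± 0.59. Of 22 monocyte genes 11 fell and 3 rose, or 15 and 3 adjusted over the list alone (camera adjusted p = 3.61e-11, but adjusted p = 0.171 with an estimated correlation), with fibronectin (Fn1) at -4.40 ± 0.31. The lectins Clec4b2 (-5.26 ± 0.62) and Clec4a2 (-3.77 ± 0.48) and the surface antigen Ly6c1 (-3.71 ± 0.32) fell, and the homeobox factor Cux2 was at least 42.8-fold lower. Of 28 ER chaperone genes 15 fell and 0 rose, or 20 and 0 adjusted over the list alone (camera adjusted p = 4.43e-06, but adjusted p = 0.208 with an estimated correlation). ER to Golgi transport was called downward with 7 of 41 lower and 1 higher, the same counts adjusted over the list alone (camera adjusted p = 0.0126, but adjusted p = 0.142 with an estimated correlation). Of 14 TRAPP subunits 2 fell, 2 also adjusted over the list alone (camera adjusted p = 0.00872, but adjusted p = 0.0705 with an estimated correlation).

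Among response lists in KO GMP library 1, 11 of 25 p53 targets rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 3.63e-08, and adjusted p = 0.0111 with an estimated correlation), with Cdkn1a at 2.01 ± 0.13 and Phlda3 at 4.58 ± 0.35. Of 24 interferon genes 11 rose and 1 fell, or 13 and 3 adjusted over the list alone (camera adjusted p = 9.33e-08, and adjusted p = 0.0116 with an estimated correlation). As in CMP the WT reference was low, with 20 of 24 members lower in WT GMP libraries 1 and 2 than in 3 and 4 and Rsad2 at -2.26 ± 0.13. The interferon list was called upward in numbers 3 and 4 too (camera adjusted p = 2.77e-10, and adjusted p = 0.0107 with an estimated correlation), with 0 passing over all genes and 3 higher adjusted over the list alone. Stromal genes rose in library 1 together with Xist (9.54 ± 0.57). Of 13, 7 rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 7.05e-09, and adjusted p = 0.0296 with an estimated correlation). The collagen Col1a2 changed by 5.44 ± 0.60, the proteoglycan Bgn by 4.75 ± 0.34, Gas6 by 5.29 ± 0.48, the transglutaminase Tgm2 by 4.96 ± 0.42 and the complement inhibitor Serping1 by 4.86 ± 1.21, with 0 CPM in WT GMP library 2 and up to 11.82 without WT GMP library 1. Sparc was 75-fold higher (counting interval 25.4 to 783) and Clca1 was 130-fold higher (44.1 to 637). Cholesterol synthesis (1 of 24 higher, 7 lower, or 1 and 11 adjusted over the list alone) was called downward (camera adjusted p = 0.00569, but adjusted p = 0.0583 with an estimated correlation). Ribosomal proteins (1 of 85 higher, 18 lower, or 1 and 22 adjusted over the list alone) were called downward as well (camera adjusted p = 2.6e-07, but adjusted p = 0.535 with an estimated correlation). Immediate early genes (8 of 23 higher, 0 lower, 8 also adjusted over the list alone) were called upward (camera adjusted p = 0.00206, but adjusted p = 0.483 with an estimated correlation), with Nr4a1 at 1.71 ± 0.18. Camera also called 5 further lists in library 1, none with an estimated correlation. ATF4 targets (4 of 22 higher, 1 lower; camera adjusted p = 0.0031) and cytokine receptors (7 and 4 of 15; 0.0327) were called upward. DNA replication (0 and 8 of 28; 0.00236), autophagy and lysosome (4 and 12 of 29; 0.00148) and oxidative phosphorylation (1 and 11 of 87; 0.000867) were called downward. In GMP numbers 3 and 4 camera called 11 lists (8 up, 3 down), 2 with an estimated correlation. Beside interferon, those upward were ATF4 targets, p53 targets, immediate early genes, heat shock, stem cells, erythroid genes and ribosome biogenesis. Monocyte, mast cell and autophagy genes were called downward. Over all libraries camera called 17 lists in GMP, 0 with an estimated correlation (smallest adjusted p = 0.134 with an estimated correlation), and without KO GMP library 1 only 5 of these 17 were called.

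The next comparison asks whether the KO effect differed between CMP and GMP. No gene passed in edgeR (0 higher, 0 lower), and 451 genes had an unadjusted p under 0.05 against 759 by chance. The 451 became 801 with a block by library number, 1165 with a block by genotype and number, and 859 without KO GMP library 1. The count without a block lay below chance and those with a block above it, so 0 calls do not show equal KO effects. DESeq2 called 3 lower, Dpep1 and Mmp27 among them. Mmp27, a matrix metalloproteinase, had the smallest adjusted p at 0.291. It held 0.213 ± 0.0904 CPM in WT CMP, 0 in KO CMP, 0.264 ± 0.127 CPM in WT GMP and 0.571 ± 0.273 CPM in KO GMP. Of the other genes with the smallest p, the AMPK subunit Prkag2 measured 0.61 ± 0.15, Cdca7 0.32 ± 0.09, Batf2 1.63 ± 0.46 and AU022252 -0.69 ± 0.18, each at an adjusted p of 1. Dtx1, Myoz1, Rhag, Kcnh5 and BB031773 completed the genes with the smallest p, also at an adjusted p of 1. Without KO CMP library 1 edgeR called Tor1aip1. Within numbers 1 and 2, with KO GMP library 1 (n = 1) as an arm whose spread is assumed, edgeR called 54 genes higher and 350 lower, and within numbers 3 and 4 it called 1 and 1 (Gm8801 and Chi3l3). Camera called 15 of 36 lists, 0 with an estimated correlation (smallest adjusted p = 0.156 with an estimated correlation). The KO effect on the granule list was lower in CMP than in GMP (camera adjusted p = 6.51e-11, but adjusted p = 0.344 with an estimated correlation) and that on DNA replication was higher (camera adjusted p = 2.66e-11, but adjusted p = 0.156 with an estimated correlation). Across 15181 genes the KO effects in CMP and GMP correlated with r = 0.376 and rho = 0.426. Without KO GMP library 1 r was 0.017 and without KO CMP library 2 it was 0.253. Within the sets r was 0.388 in numbers 1 and 2 (with KO GMP library 1 alone) and 0.031 in numbers 3 and 4. Across the 10480 genes with at least 5 CPM, r was 0.538 over all libraries, 0.67 in numbers 1 and 2 and 0.42 in numbers 3 and 4.

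GMP against CMP in WT gives the step between the sorted populations. Eosinophil ribonuclease genes had the largest rise in GMP (n = 4 in each group), with Ear1 at 6.80 ± 1.22, Ear2 at 6.28 ± 1.06, Ear3 at 6.19 ± 1.09, Ear7 at 6.15 ± 1.08 and Ear6 at 6.08 ± 1.22, though reads can be shared within this family. The carbonic anhydrase Car1 (-7.35, adjusted p = 0.000286), the lymphoid polymerase Dntt (-7.16 ± 0.78), the homeobox factor Nkx2-3 (-6.47 ± 0.75), the channel Trpc6 (-6.09 ± 0.88) and the endothelial receptor Robo4 (-5.89 ± 1.10) fell. Of the sorting markers Fcgr3 (1.96 ± 0.40) and Fcgr2b (0.99 ± 0.13) rose, and Cd34 (-1.19 ± 0.25), Kit (-0.36 ± 0.12) and Ly6a (-2.65 ± 0.53) fell. Kit was not called without WT CMP library 1, 2 or 3 or WT GMP library 1, 3 or 4 (-0.38 to -0.31). In all, 1721 genes were higher and 2151 lower in GMP. The count of genes higher was 950 without WT CMP library 3, 1119 without WT GMP library 3, 1078 without WT GMP library 4, 1130 with upper-quartile factors and 2758 with a block by genotype and number. With upper-quartile factors the share of called genes that were higher moved from 44.4% to 31.3%. Within the number sets, 1672 were higher and 2119 lower in numbers 1 and 2, and 2917 and 2934 in numbers 3 and 4.

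Mast cell, basophil and eosinophil genes rose in WT GMP, 15 of 21 higher and 0 lower, or 15 and 1 adjusted over the list alone (camera adjusted p = 5.06e-13, and adjusted p = 0.0274 with an estimated correlation), with Mcpt8 at 2.88 ± 0.20. Of 17 granule genes 15 rose, or 17 adjusted over the list alone (camera adjusted p = 5.83e-10, but adjusted p = 0.199 with an estimated correlation). Of 28 ER chaperone genes 23 rose and of 41 ER to Golgi genes 26 rose, or 24 and 30 adjusted over the list alone (camera adjusted p = 1.76e-13 and 4.9e-12, but adjusted p = 0.131 with an estimated correlation for each). Of 14 TRAPP subunits 4 rose, 4 also adjusted over the list alone (camera adjusted p = 0.00743, but adjusted p = 0.131 with an estimated correlation). Of 28 genes of the G2 and M phases 20 rose, or 23 adjusted over the list alone (camera adjusted p = 2.52e-11, but adjusted p = 0.0645 with an estimated correlation). Of 19 stem cell genes 18 fell, 18 also adjusted over the list alone (camera adjusted p = 5.15e-20, but adjusted p = 0.0747 with an estimated correlation), with the receptor Flt3 at -3.00 ± 0.33. Of 23 erythroid genes 16 fell and 1 rose, the same counts adjusted over the list alone (camera adjusted p = 8.05e-11, but adjusted p = 0.0645 with an estimated correlation), and the red cell genes Rhag and Add2 were at least 37-fold and 31.4-fold lower. Of 18 megakaryocyte genes 14 fell and 1 rose, the same counts adjusted over the list alone (camera adjusted p = 6.99e-12, but adjusted p = 0.131 with an estimated correlation). T and NK genes (13 of 17 lower, 14 adjusted over the list alone, camera adjusted p = 1.22e-08) and dendritic cell genes (13 of 17 lower, 14 adjusted over the list alone, camera adjusted p = 2.3e-09) fell too, each with an adjusted p = 0.131 with an estimated correlation. Of 15 B lineage genes 7 fell, 7 also adjusted over the list alone (camera adjusted p = 0.000478, but adjusted p = 0.175 with an estimated correlation).

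GMP against CMP in KO gives the same step in KO cells, where KO GMP libraries 3 and 4 held Trappc1 at 24.1 and 25.2 CPM. Here 1631 genes were higher and 1594 lower in GMP (n = 3) than in CMP (n = 4). Of these, 1162 and 1336 were also called in WT in the same direction, where independent calls would give 185 and 226, and 0 were called in opposite directions. Ear1 (7.59 ± 1.31), Ear2 (7.07 ± 1.16), Ear3 (7.07 ± 1.17), Ear7 (8.09 ± 1.23) and Ear6 (7.85 ± 1.40) rose, and Car1 (-4.19 ± 0.91), Dntt (-6.04 ± 0.83), Nkx2-3 (-3.55 ± 0.71), Trpc6 (-2.98 ± 0.81) and Robo4 (-3.71 ± 1.09) fell. Fcgr3 (3.42 ± 0.44) and Fcgr2b (1.52 ± 0.14) rose, Cd34 (-1.13 ± 0.28) and Ly6a (-2.19 ± 0.57) fell, and Kit measured -0.18 ± 0.13 (adjusted p = 0.384). Without KO GMP library 1 these were -6.50 for Car1, -4.84 for Trpc6, -5.65 for Robo4, -1.71 for Cd34 and -0.37 for Kit, which was then called. Without KO GMP library 3 Trpc6, Robo4, Cd34 (-0.92) and Ly6a were not called. Without KO GMP library 4 Robo4 (-3.13), Cd34 (-0.89) and Ly6a were not called. All 17 granule genes rose, 17 also adjusted over the list alone (camera adjusted p = 7.97e-20, but adjusted p = 0.125 with an estimated correlation), and 17 of 21 mast cell, basophil and eosinophil genes rose, or 18 with 1 lower adjusted over the list alone (camera adjusted p = 8.33e-17, and adjusted p = 0.00763 with an estimated correlation). Of 19 stem cell genes 18 fell, 18 also adjusted over the list alone (camera adjusted p = 8.91e-15, but adjusted p = 0.125 with an estimated correlation). The counts rest partly on single libraries. Higher and lower genes numbered 969 and 687 without KO GMP library 3, 1021 and 742 without KO GMP library 4, 2029 and 2361 without KO GMP library 1, and 1018 and 858 with only the KO libraries in the fit. With upper-quartile factors the share of called genes that were higher moved from 50.6% to 39.1%. Within the number sets, 1278 were higher and 1056 lower in numbers 1 and 2 (KO GMP n = 1, its spread assumed), and 2715 and 2905 in numbers 3 and 4.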

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

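The tests of depth, of undeleted cells, of the extent of Trappc1 loss, of library KO GMP 1 as a CMP library or as CMP cells alone, and of the source of Xist were chosen only after the result was seen.

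The KO effect differed between the number sets, which drew attention because the difference itself passed a test. It differed for 1160 genes in CMP and 1614 genes in GMP, and for Trappc1 by -1.45 in CMP and -2.3 in GMP. Lower depth in numbers 3 and 4 is argued against by mean totals of 97.22 M units in that set and 73.51 M in numbers 1 and 2. The step from CMP to GMP in WT called 5851 genes in numbers 3 and 4 and 3791 in numbers 1 and 2. That count also depends on the size of the step in each set, so it does not measure power alone. A difference between the sets shared by both genotypes would part KO libraries as well as WT libraries, without placing the changed KO effect in either. In GMP the KO arm of numbers 1 and 2 is a single library, KO GMP 1, whose spread is assumed. The KO libraries of the sets differed for 29% of all tested genes in CMP, so WT libraries do not stand apart alone there. Of the 1160 and 1614 genes 62.8% and 84.9% differed so in the direction of the set difference, against 20.6% and 18.5% of the other genes, though choosing genes by the set difference raises these shares. The WT libraries of the sets differed for 57.8% of these genes in CMP and 16.5% in GMP, so WT libraries take part in CMP. Cells with undeleted Trappc1 mixed into KO libraries 3 and 4 would keep 54.1% of the change in CMP by the Trappc1 level, and the median gene kept 17.4% (upper quartile 39.3%) of the 1551 called lower in numbers 1 and 2. Choosing genes by that effect can lower the share. Genes chosen on libraries 1 and measured on libraries 2 kept 27.5% (upper quartile 55.4%), the reverse choice gave 18% (33.1%) and genes stable between the WT sets 21.7% (42.6%), so this cannot be told apart from other explanations. This share is a ratio of losses, so reads from remaining exons cancel in it where the same part is deleted in all libraries. In GMP the share kept was 4.92% (upper quartile 20.9%) against 27.5% expected with a wide error, so this stays open there too. The extent of Trappc1 loss, with its difference of -1.45, and an effect of batch may each contribute, and they cannot be told apart because the extent of loss goes with the number set.

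KO GMP library 1 lay nearer to the CMP libraries than any other GMP library. CMP cells mixed with GMP like those of WT, as the whole cause, would give the same share from genes higher and genes lower in CMP. The share was 31.1% (quartiles 22.2 to 43.6) from genes higher in CMP and 70% (54.1 to 84.9) from genes lower in CMP. Genes were chosen by the same means that set the end points, which moves these shares apart in this direction by an unmeasured amount. The gap therefore does not settle the question. The 1.34% of tested genes above or below both sources, such as Cma1 at 38 CPM against 0.275 and 1.15, decide nothing, since KO CMP 1 taken alone gave 1.09%. A CMP library labelled GMP cannot be told apart by the 2334 genes that differ from KO CMP libraries 1 and 2, with the spread of the 1 library assumed, since other single CMP libraries gave 1316 to 3448 (KO CMP 1 and 2 differed from each other for 268). Nor is it settled by KO GMP 1 lying beyond all CMP libraries on the GMP side for 39% of the 5851 step genes, where CMP libraries reached 32.3% and WT GMP libraries 72.9% or more. A mixture with CMP cells, a wrong label and an effect of genotype in GMP, as a hypothesis resting on 1 library, stay open.

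Xist stood at 109, 204 and 123 CPM in KO CMP libraries 1 and 2 and KO GMP library 1. Cells of female animals may be a source, since the summed Y-linked genes were 81.2% of WT in KO CMP 1 and 2 and 77.1% in KO GMP 1. The 162 CPM of KO GMP 1 lay below all other GMP libraries (188 to 213 CPM). Among the 3 libraries, though, the sum was highest (187 CPM, against 166 and 162) where Xist was highest. WT CMP 4, KO CMP 3 and KO CMP 4 with Xist under 1 CPM held 170, 173 and 177 CPM, so this stays open. Stromal cells would carry Xist, the X-inactivation RNA, if they came from female animals, so they are not a source apart from female cells. The ratio of Xist to the 9 stromal list genes under 5 CPM in WT varied 2.62-fold among the 3 libraries (1.85, 2.32 and 4.84). This leaves open whether stromal cells carried it. Of 13 tested stromal list genes, 4 reach 5 CPM in the WT groups and 0 are in another list. Cxcl12 stood at 91, 127 and 48.7 CPM and Col1a2 at 24, 34.4 and 9.62 CPM. In KO CMP 1 and 2 Lepr (4.73 and 6.5) and Pdgfra (1.32 and 2.67) lay above the WT CMP means of 0.372 and 0.112. Cdh5 (0.0544 and 0) and Kdr (1.43 and 1.56) were not raised alike there, against 0.424 and 1.22. Pecam1 (134, 113 and 160) and Vcam1 (8.14, 31.9 and 33) were not raised alike either. WT CMP already held them at 133 and 51.3 CPM, so their levels say little about stromal cells. The gate asked for lineage-negative CD117-positive cells, and how far it left out stromal cells was not tested.

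Single libraries stood far from the others of their group in 7 of 186 groups tested, where chance gives about 1 in 20, or 9. Only groups of 4 libraries were tested, so KO GMP (n = 3) was left out. Its library 1 lay at -17.2 on PC1, against 81.2 and 85.3 for KO GMP libraries 3 and 4. The gap over the range was 0.916 for Rn45s in KO CMP 1 and 0.839 for Clec4a2 in WT GMP 4. It was 0.892 for Fcnb in KO CMP 1 and 0.963 for Trpc6 in WT GMP 2. It was 1 for Col3a1 in WT GMP 2 and for Tpsb2 in WT CMP 4 and in KO CMP 3, where the other libraries held 0.

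Effects on 15 lists differed between CMP and GMP by camera, and 0 did with an estimated correlation.

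Other splits of the libraries were counted beside the real ones. For KO against WT edgeR called 0 genes in CMP (1761 at an unadjusted p under 0.05, 360 by DESeq2) and 0 in GMP (985 and 60), and the highest other split gave 2400 and 296. With a real count of 0 every split gives as many (35 of 35 in each), so the count of splits says nothing here. Those splits follow the number sets and point to a structure of the libraries. For the difference between cell types, the same holds for 100 of 100 splits against the real 0 (451 at an unadjusted p under 0.05, 3 by DESeq2), with 38 the highest other, again a split near the number sets. For GMP against CMP the real split called the most genes in each genotype. In WT it called 3872 genes (1 of 35 splits as large, highest other 21). In KO it called 3225 genes (1 of 35, highest other 1842). A share of 1 in 35 is the smallest that these splits allow, so they cannot exclude chance beyond it. The 1842 came from a split joining KO GMP 1 to KO CMP 1 and 2, and among the 8 splits parting as many pairs the highest other was 0 in WT and 7 in KO.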

How the results depend on the processing

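Number set as a covariate, values divided by 4, and all alternatives within number sets were chosen only after the result was seen. Of the counts, 216 planned and 92 added values stayed within 1.5 times the reported count, and 28 and 40 moved. Of gene list results, 1558 kept direction and side of the threshold, 212 lost their call and 10 reversed. The cause was not tested for any change below except where the alternative asks for a larger effect or a smaller p.

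With DESeq2 KO against WT called 133 genes higher and 227 lower in CMP, 48 and 12 in GMP, 3 lower for the difference between cell types, 73 and 65 in CMP numbers 3 and 4, 13 and 30 in GMP numbers 3 and 4, and 810 higher for the set difference in CMP. Trappc1 passed with DESeq2 in CMP (-1.36, adjusted p = 0.0267) and in CMP numbers 3 and 4 (-0.81, adjusted p = 0.017). With the number set as a covariate 4 genes were higher and 1 lower in KO GMP. For GMP against CMP in WT, upper-quartile factors gave 1130 higher and a block by genotype and number gave 2758. At an adjusted p of 1% there were 656 and 1152 in WT and 931 and 705 in KO, and at 1.5-fold by glmTreat 87 and 845 in WT and 371 and 475 in KO. With only the 2 groups compared the KO counts were 1018 and 858. In a number set alone CMP numbers 1 and 2 had 808 higher, CMP numbers 3 and 4 had 4 and 15, GMP numbers 1 and 2 had 827 lower, and GMP numbers 3 and 4 had 3 and 8. Fitting numbers 1 and 2 alone also called fewer genes for the difference between cell types and for GMP against CMP in KO, which both use KO GMP library 1. Without the low-count filter CMP numbers 3 and 4 had 2 and 2, GMP numbers 3 and 4 had 3 and 9, and the correlation of KO effects was 0.142. Divided by 4, GMP numbers 3 and 4 had 2 and 7 and the correlation was 0.507.

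Leaving out each library in turn, KO against WT in CMP ran from 0 to 2 higher and 0 to 48 lower (48 without WT CMP 4, 1 without KO CMP 1), and the difference between cell types from 0 to 1 lower (1 without KO CMP 1). GMP against CMP ran from 950 (without WT CMP 3) to 2000 higher in WT, with 1119 and 1078 without WT GMP 3 and 4. In KO it ran from 969 to 2029 higher and 687 to 2361 lower, lowest without KO GMP 3 and next without KO GMP 4 (1021 and 742). CMP numbers 1 and 2 ran from 722 (without WT CMP 2; 814 without WT CMP 1) to 1172 higher. CMP numbers 3 and 4 ran from 0 (without KO CMP 3 or 4) to 1 higher and from 0 to 4 (without KO CMP 3) lower. GMP numbers 1 and 2 ran from 757 (without WT GMP 1) to 1037 lower. GMP numbers 3 and 4 ran from 1 to 3 higher (3 and 2 without WT GMP 3 and 4) and from 0 (without WT GMP 3, WT GMP 4 or KO GMP 4) to 5 lower (without KO GMP 3). The set difference in CMP ran from 208 (without KO CMP 4) to 522 higher, with 261, 287 and 278 without WT CMP 2, WT CMP 3 and KO CMP 3. In GMP it ran from 324 (without KO GMP 4) to 503 lower, with 372, 330, 427 and 349 without WT GMP 1, WT GMP 3, WT GMP 4 and KO GMP 3. The correlation of KO effects ran from 0.017 (without KO GMP 1) to 0.394, with 0.253 without KO CMP 2.

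Reversals came from leaving out libraries. Ly6a in CMP numbers 3 and 4 ran from -0.02 (without WT CMP 3) to 0.36, and Fcgr3 in GMP numbers 3 and 4 from -0.07 to 0.01 (without KO GMP 4). Hba-a1 in GMP numbers 3 and 4 ran from -3.04 (without KO GMP 3) to 9.59, fitted values that rest on a side near 0. Without KO GMP 1 the direction of list tests in GMP reversed, with ranges of medians given, for megakaryocytes (-0.02 to 1.42), dendritic cells (0.06 to 1.37, where the median kept its sign), stroma (-0.25 to 4.00), ribosomal proteins (-0.16 to 0.04), ER chaperones (-0.16 to 0.04) and DNA replication (-0.06 to 0.00). For the difference between cell types they reversed for oxidative phosphorylation (-0.03 to 0.19), ribosomal proteins (-0.06 to 0.19), stem cells (-0.80 to 0.19) and erythroid cells (-0.57 to 0.24). Scaling moved the median of all genes by at most 0.083 in size. Depth limits genes with few fragments, and the filter left 15181 genes against 18161 without it and 14011 with the stricter filter.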

Other observations

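The comparison of WT libraries between number sets and the correlations with the step from CMP to GMP were chosen only after the result was seen.

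WT libraries 1 and 2 differed from WT libraries 3 and 4 with no change of genotype, for 3479 genes in CMP (1863 higher, 1616 lower) and 1307 in GMP (479 higher, 828 lower). The sets were chosen because these same WT libraries part that way. The counts and p-values here therefore describe that split and are no test of it. Interferon response genes fell in both cell types, 21 of 24 lower in CMP (adjusted p = 8e-05 with an estimated correlation) and 20 lower in GMP. The antiviral Rsad2 measured -1.77 ± 0.11 in CMP (adjusted p = 1.37e-06) and -2.26 ± 0.13 in GMP. Granule genes rose in CMP, 16 of 17 higher and 0 lower (adjusted p = 0.00382 with an estimated correlation), with Elane at 1.74 ± 0.14. Late neutrophil genes moved in opposite directions, 12 higher and 3 lower of 19 in CMP and 1 higher and 11 lower in GMP. S100a8 measured 4.27 ± 0.32 in CMP and Chi3l3 measured 2.42 in CMP and -2.25 in GMP. Histone genes fell, 36 of 65 lower in CMP and 22 in GMP, though not with an estimated correlation (adjusted p = 0.242 and adjusted p = 0.415).

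The KO effect in numbers 1 and 2 ran against the step from CMP to GMP measured in WT libraries 3 and 4, which share no library with it. Across 10480 genes with at least 5 CPM r was -0.624 in CMP and -0.698 in GMP (rho -0.509 and -0.549), the GMP value from KO GMP library 1 alone. The KO effect in numbers 3 and 4 against the WT step of numbers 1 and 2 gave an r of 0.173 in CMP and -0.062 in GMP, with rho at 0.27 and 0.071, of opposite sign in GMP. Fitting numbers 3 and 4 alone called 4 genes higher and 15 lower in CMP and 3 higher and 8 lower in GMP. In both cell types the immunoglobulin joining chain Igj (-2.14 in CMP, -2.40 in GMP), 2010001M09Rik (-2.46 and -3.08), a plasma cell gene, Prss34 (-1.18 and -1.05), Cyp4f18 (-1.05 and -0.84) and Pld4 (-0.66 and -0.67) fell, and Atf3 rose (0.78 and 0.85). These genes are named because they were called, after their values were seen. Deviations of KO CMP and KO GMP libraries correlated at 0.326 for number 3 and 0.355 for number 4. The 2 cell types are therefore not independent repeats of a KO effect.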
